A study of Mus musculus with 12 samples.

How the data were processed

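The series measured RNA of meningeal lymphatic endothelial cells, the cells that line the lymph vessels of the membranes around the brain, from mice 20 weeks old. Per the labels, cells were taken by magnetic sorting from 3 to 4 mice of each strain, and 500 ng of total RNA entered a Lexogen QuantSeq library, a kit that reads transcripts near their ends. The 12 libraries fall into 3 groups of 4 by their titles: SJL_B6, AD_B6 and AD_TG. The labels do not spell out these abbreviations and give 1 strain for all samples. They do not say whether the 4 libraries of a group came from separate animals, so every p-value measures only the spread between these samples. If a strain had 3 mice in all, its 4 libraries cannot all come from separate animals.

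The authors deposited log2 values per gene symbol, 1 file per library. The values were log2(x + 1) of scaled amounts, whose linear totals ran from 6216992 to 7872830 per library, and the scaling method is not stated in the labels. Per the submitters' processing notes, Bowtie2, bedtools and the build hg19 were used, with no versions. That build is human, whereas the organism and the symbols are those of the mouse; no coordinates were used here. The mouse reference served only to match symbols, and 23152 of 23238 symbols (99.6%) matched a current symbol or a synonym. Each file held 23282 entries; of 35 symbols with more than 1 entry, the entry with the highest mean was kept and 44 were left out.

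The depth was estimated from the files. On the linear scale, the low values of each library lay on even steps of 0.698 to 1.76, taken as the value of 1 read, and 90.5 to 100% of the values below 20 lay within 0.15 of a whole number of steps. The linear total divided by the step gave 4013140 to 9317207 assigned reads per library. A gene was said to have reads in a library at a linear value of 0.3 or more, since some libraries list their other genes at a small value above 0.

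A count model had been chosen before the data were examined, with limma on log2 values as the stated fallback should the files hold no counts, and the fallback was used. The 11955 genes with a linear value of at least 10 in at least 4 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend) on the deposited log2 values. All 12 libraries entered 1 fit, so the groups shared 1 estimate of the spread per gene. The 3 contrasts were AD_B6 against SJL_B6, AD_TG against AD_B6 and AD_TG against SJL_B6, two-sided, with a Benjamini-Hochberg adjusted p below 0.05 as the threshold. A further count compared genes of opposite signs in the contrasts that share AD_B6, beside 20 simulations of unchanged groups, made by shuffling the residuals of each gene separately, which removes any correlation between genes. Single values per library were compared with exact two-sided permutation tests, whose smallest p with 4 against 4 is 0.0286.

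Of 35 gene lists, 3 had fewer than 5 tested members, the sex-linked list was a sample check and was not tested with camera, and the other 31 were tested with camera of limma, with the correlation between genes estimated per list and adjustment over the lists of a contrast. Camera compares a list with the other genes. The lists of cell types were lymphatic endothelial identity, pan-endothelial, mural cell, macrophage, neutrophil and granule, erythroid, B cell, T and NK cell, meningeal fibroblast, neuron, myelinating glia, astrocyte, choroid plexus, pineal, skeletal muscle, and bone and cartilage. The other lists were calcineurin-NFAT components, NFAT and VEGF response, lymphangiogenic signalling, Notch, junctions, basement membrane, interferon response, inflammatory cytokine, MHC class I, MHC class II, immediate early, cell cycle, amyloid processing and clearance, nuclear oxidative phosphorylation, glycolysis and hypoxia, unfolded protein response, cholesterol synthesis, neighbours of Rcan1 on its chromosome, and sex-linked genes as a sample check. The lists named 443 genes, of which Ighm, Igkc, Ly6g, Ahsp, Trac and Vegfd were not among the symbols.

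The genes named in the text were Rcan1, App, Prox1, Lyve1, Flt4, Pdpn and Pecam1 in every contrast; 1 other gene fixed in advance is not reported here. Where no gene passed, the rule added the 5 genes per direction with the smallest unadjusted p and a mean log2 CPM of 3 or more, given as values that did not pass. Members of the lists are named as examples, and those were chosen after their values were seen.

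The fit was tested on the values of the 11955 genes after shuffling them between the 12 libraries within each gene, with 33 or 34 genes changed at each of 3 folds and 2 levels. For AD_B6 against SJL_B6, 60.6% of the 4-fold changes and 100% of the 16-fold changes were recovered among genes with a mean log2 of 10 or more, and 15.2% of the 16-fold changes among genes with a lower mean. For AD_TG against AD_B6 these shares were 48.5, 100 and 18.2%, and for AD_TG against SJL_B6 27.3, 100 and 15.2%. Of the 2-fold changes at the higher mean, 2.94, 2.94 and 5.88% were recovered. The shuffled genes left unchanged gave 1, 3 and 0 false calls. The folds multiplied the linear values, so entries at 0 stayed at 0. These shares therefore do not measure the recovery of genes with reads in 1 group and none in another.

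The alternatives were another scaling, other filters, another pseudocount, the replicate number as a block, only the libraries of the groups compared, the removal of haemoglobin, immunoglobulin and mitochondrially encoded genes, and each library left out in turn. For the lists, a preset correlation of 0.01 was tried. Array quality weights, a pseudocount of 50, only the genes with reads in all 12 libraries, the removal of Rn45s, Rn4.5s and Ttr, the weights without AD_B6 replicate 3, exact permutation tests of list means, the number of genes with reads without AD_B6 replicate 3, and exact tests of Xist and of the Y-linked genes were added after seeing the data.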

Results

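The 12 libraries describe cells enriched from the mouse meninges as lymphatic endothelium, with 4 libraries each labelled SJL_B6, AD_B6 and AD_TG. All values are deposited log2 values unless another unit is given. Estimated assigned reads ran from 4013140 to 9292537 in SJL_B6, from 5469187 to 8906610 in AD_B6 and from 4148811 to 9317207 in AD_TG. Genes with at least 1 read numbered 11431 ± 584 in SJL_B6, 10289 ± 1125 in AD_B6 and 11537 ± 409 in AD_TG (SD, n = 4), with the lowest number, 8748, in AD_B6 replicate 3. The exact permutation p for these numbers was 0.0857 for AD_B6 against SJL_B6 and 0.0571 for AD_TG against AD_B6 (both 0.321 after adjustment over 15 tests of library measures). Of 23238 symbols, 17256 had reads in at least 1 library and 4950 in all 12. The correlation across genes between libraries had a median of 0.468 within groups and 0.469 between groups; genes are not independent replicates.

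**Figure D1:**
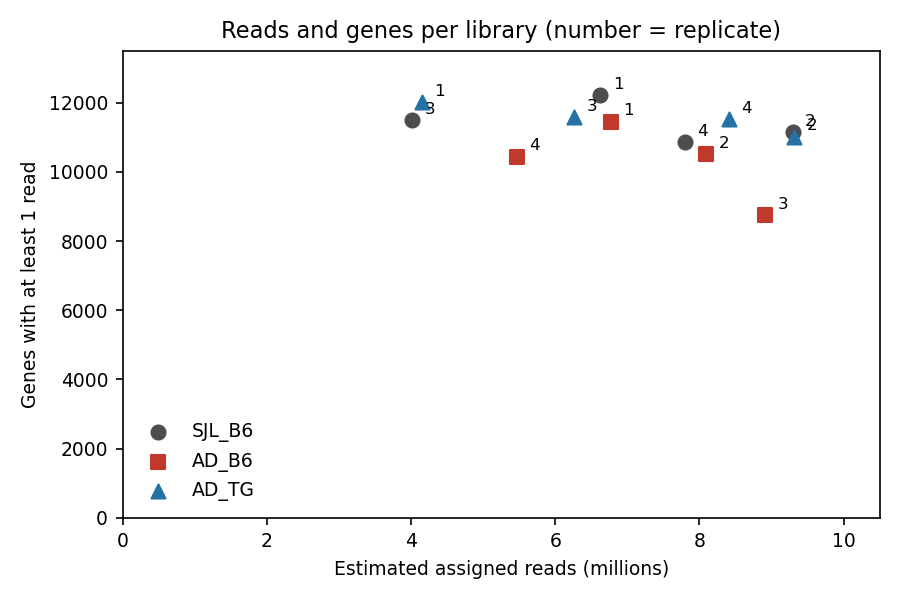
Genes with at least 1 read (vertical axis) against estimated assigned reads (horizontal axis, in 1e6 reads), 1 point per library, with the replicate number beside it. AD_B6 replicate 3 held 8748 genes and the other libraries lay between 10438 and 12217.

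The most abundant transcripts came from several kinds of cells. After Rn45s, the ribosomal RNA precursor (19.03 ± 0.59, SD, n = 12), came Ttr, the transthyretin gene of choroid plexus epithelium (17.41 ± 1.90), the nuclear RNA Malat1 (16.43 ± 0.55) and Enpp2, the gene of the secreted enzyme autotaxin (15.53 ± 1.88). The antigen presentation genes H2-Eb1 and H2-Aa stood at 14.06 ± 0.55 and 14.01 ± 0.46, the collagen gene Col1a2 of fibroblasts at 13.29 ± 0.75 and the macrophage receptor gene Csf1r at 12.46 ± 0.45. Among genes of the lymphatic endothelial list, Nr2f2, a transcription factor of venous and lymphatic identity, stood at 10.25 ± 0.58. Pdpn, which encodes podoplanin, stood at 9.31 ± 0.87 and Nrp2, a co-receptor of lymphatic growth factors, at 9.16 ± 0.67. Which cells these transcripts came from was not tested, so their levels alone do not show lymphatic endothelium. Prox1, the master regulator of lymphatic fate, had reads in 2 of the 12 libraries. It stood at 8.38 in SJL_B6 replicate 1 and 0.88 in SJL_B6 replicate 4, and was listed at 0 or below the value of 1 read in the others. Flt4, the receptor of VEGF-C, had reads in 6 of the 12 libraries, and Pecam1, a junction protein of endothelium, in 8.

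Averaged over all their members, the choroid plexus list stood at 11.06 ± 1.91, the macrophage list at 10.22 ± 0.60 and the meningeal fibroblast list at 8.07 ± 1.14 (SD, n = 12). The lymphatic endothelial list stood at 4.44 ± 0.83 and the pan-endothelial list at 4.79 ± 0.96. The 15 lymphatic endothelial genes made up 0.0434 to 0.0764% of each library, the 16 macrophage genes 0.257 to 0.781% and the 7 choroid plexus genes 0.236 to 8.67%. Genes of B cells (1.74 ± 0.58), T and NK cells (0.70 ± 0.37) and skeletal muscle (1.38 ± 0.82) were low, and fewer than 5 members of each list could be tested.

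**Figure D2:**
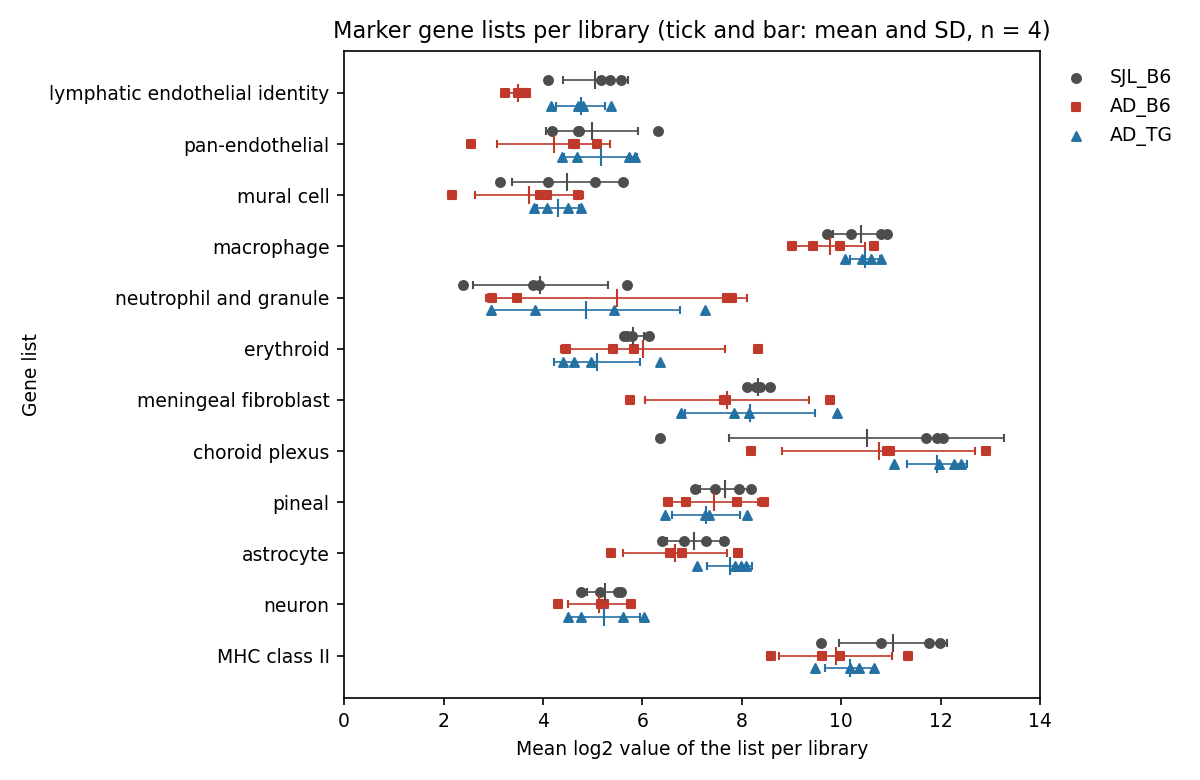
Mean log2 value of all members of 12 gene lists (horizontal axis), 1 point per library, with a tick and bar for the mean and SD of the 4 libraries of a group. Macrophage, choroid plexus and MHC class II genes lie to the right of the lymphatic endothelial genes in all 12 libraries, and SJL_B6 replicate 2 lies apart at 6.36 for choroid plexus.

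The series title concerns DSCR1, an inhibitor of the phosphatase calcineurin, whose mouse gene is Rcan1. Rcan1 stood at 9.05, 5.21, 7.16 and 8.18 in SJL_B6 replicates 1 to 4, at 8.74, 9.55, 9.54 and 7.34 in AD_B6 and at 6.47, 9.28, 7.54 and 7.70 in AD_TG. The libraries labelled AD_TG thus had 7.75 ± 1.16 against 8.79 ± 1.04 in AD_B6 (SD, n = 4), a difference of -1.04 with a 95% interval of -3.18 to 1.099 and an adjusted p of 0.903 in limma. A kit that reads transcript ends can miss a transgene of another species or with another end, so this value does not check the label.

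The comparison of AD_B6 with SJL_B6 asks what goes with the AD label. The titles differ in the SJL label as well, so a difference that goes with AD cannot be told apart from one that goes with SJL. The 9 tested lymphatic endothelial genes averaged 5.59 ± 0.39 in AD_B6 and 7.45 ± 0.44 in SJL_B6 (SD, n = 4), and 8 of the 9 were lower in AD_B6. Reln, the gene of a glycoprotein secreted by lymphatic endothelium, stood at 7.66, 5.14 and 7.08 in SJL_B6 replicates 2 to 4 and was listed at 0 or below the value of 1 read in replicate 1 and in all 4 AD_B6 libraries. Itga9, the integrin of lymphatic valves, ran from 3.35 to 8.54 in SJL_B6 and had reads in 1 AD_B6 library, at 4.92. Nr2f2 differed by 0.19 (SE 0.51) and Pdpn by -0.12 (SE 0.69). No member passed; camera gave p = 0.0557 (adjusted p = 0.964), and the exact permutation test of the list means gave p = 0.0286, the smallest possible, adjusted to 0.886 over the lists. AD_B6 was also the group with the fewest genes with reads, and the lower values were not confined to this list, since 22 of the 31 lists had a negative median. Lower in AD_B6 were 5 of 7 mural cell genes (mean difference -1.31), 12 of 17 pan-endothelial genes (-0.79) and 4 of 6 myelinating glia genes (-1.09), with exact permutation p-values of 0.171, 0.457 and 0.343. After subtracting each library's mean over all genes tested, the lymphatic endothelial list differed by -1.39 (exact permutation p of 0.0286, adjusted 0.886). The mural cell, pan-endothelial and myelinating glia lists then differed by -0.84, -0.32 and -0.62 (exact permutation p of 0.514, 0.886 and 0.571).

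All 7 tested MHC class II genes, which present antigen, were lower in AD_B6 (camera of limma, adjusted p = 0.964). Cd74, the invariant chain, stood at 12.34 ± 0.32 against 13.26 ± 0.78 in SJL_B6, H2-Ab1 at 12.22 ± 0.33 against 13.05 ± 0.61 and H2-Aa at 13.69 ± 0.24 against 14.30 ± 0.56 (SD, n = 4). Adjusted over the list alone, limma gave these 3 genes adjusted p-values of 0.0387, 0.0387 and 0.0469, and 0.869 each over all genes tested. No member passed over the list alone without SJL_B6 replicate 2 (lowest 0.190), SJL_B6 replicate 3 (0.0899), AD_B6 replicate 2 (0.0751) or AD_B6 replicate 4 (0.139). Of the 16 macrophage genes, 14 were lower, among them Csf1r by -0.77 (SE 0.28), with an exact permutation p of 0.200 for the list means. Of the 9 neutrophil genes, 8 were higher, including the calprotectin gene S100a9 by 1.99 (SE 0.81), with an exact permutation p of 0.400 for the list means. Of the 11 genes of the NFAT and VEGF response, 9 were higher, and of the 14 calcineurin-NFAT components, 8 were, with exact permutation p-values of 0.200 and 0.886 for the list means.

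App, the gene of the amyloid precursor protein, stood at 13.02 ± 0.22 in AD_B6 and 12.66 ± 0.29 in SJL_B6 (SD, n = 4), a difference of 0.36 (SE 0.24). Rcan1 had 8.79 ± 1.04 and 7.40 ± 1.65, a difference of 1.39 (SE 1.04). Pdpn had 9.39 ± 0.79 and 9.52 ± 1.25. Lyve1, the hyaluronan receptor of lymphatic endothelium, ran from 7.79 to 10.39 in SJL_B6 and was listed at 0 in AD_B6 replicate 3, beside 8.53 to 9.24 in the other AD_B6 libraries. Flt4 had reads in 1 AD_B6 library, at 7.33, and in 2 SJL_B6 libraries, at 8.82 and 7.69. Pecam1 had reads in 3 libraries of each group, at 4.37 to 9.85 in AD_B6 and 6.24 to 7.67 in SJL_B6. Prox1 had no AD_B6 library at 1 read or more.

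Among the genes with the smallest unadjusted p, Mid1ip1, a regulator of fat synthesis, stood at 10.28 ± 0.56 in AD_B6 and 6.35 ± 3.73 in SJL_B6 (SD, n = 4), and Nrxn2, which encodes the adhesion protein neurexin 2, ran from 4.69 to 9.40 and from 9.49 to 10.62. Dgcr8, a partner of Drosha in making microRNA, stood at 8.59 ± 0.50 in SJL_B6 and R3hcc1l at 7.35 ± 0.29, and both were listed at 0 or below the value of 1 read in all 4 AD_B6 libraries. Rbm4, a splicing regulator, ran from 7.98 to 9.85 in SJL_B6 and stood at 0.95, 6.99, 0 and 1.86 in AD_B6; the overlapping gene Gm21992 shared these AD_B6 values. In the other direction, AD_B6 ran from 8.95 to 10.03 for Pygl, a glycogen phosphorylase, and from 7.45 to 8.49 for Plod2, a collagen-modifying enzyme, where SJL_B6 had 1 and 2 libraries at 0 or below 1 read and the rest at 4.16 to 7.82 and 1.76 to 4.19. Gulp1, an engulfment adaptor, ran from 6.10 to 9.40 in AD_B6 and had 2 SJL_B6 libraries with reads, at 1.63 and 3.51. Fam219b ran from 8.22 to 9.48 and had 1 SJL_B6 library with reads, at 9.41.

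**Figure D3:**
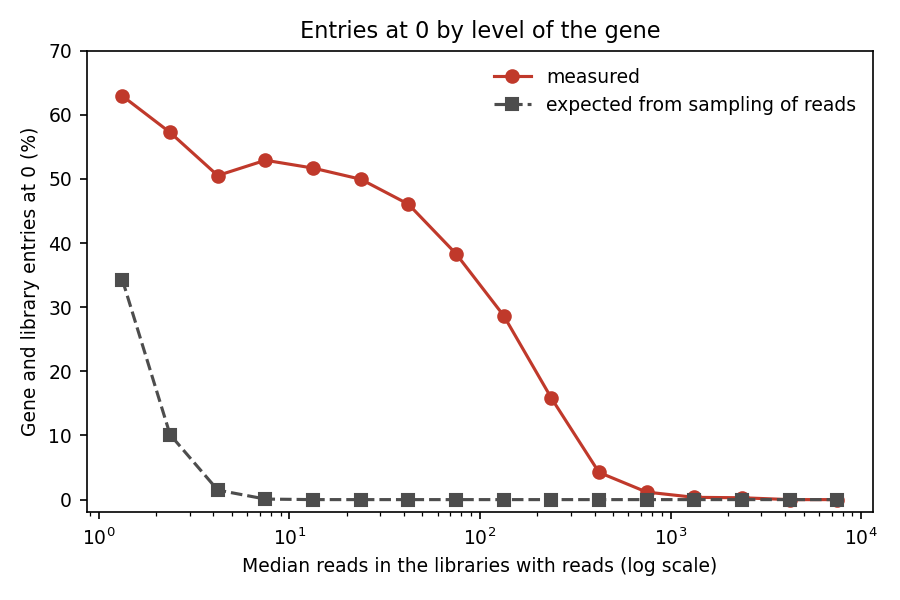
Percent of entries listed at 0 or below 1 read (vertical axis) against the median reads of a gene in the libraries that hold it (horizontal axis), as measured and as sampling of reads alone would give, with genes grouped by level. At a median of 100 to 178 reads, 28.7% of the entries of 2826 genes were at 0, where sampling gives 5.15e-44%.

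Limma called 0 of 11955 genes, with a lowest adjusted p of 0.869, and no other tool was run. At an unadjusted p under 0.05 there were 647 genes, 163 higher and 484 lower in AD_B6, beside 597.75 expected by chance. The size of the imbalance moved with single libraries. Without SJL_B6 replicates 1 to 4 there were 186, 192, 211 and 193 higher and 382, 414, 374 and 431 lower. Without AD_B6 replicates 1 to 4 there were 157, 143, 192 and 158 higher and 726, 594, 492 and 602 lower. Among the 4950 genes with reads in all 12 libraries, 105 were higher and 140 lower. The median difference over all genes tested was -0.31. The median or mean of 12 of the 31 lists differed in sign from camera, which compares a list with the other genes, namely erythroid, meningeal fibroblast, neuron, choroid plexus, pineal, lymphangiogenic signalling, Notch, junctions, basement membrane, interferon response, unfolded protein response and the neighbours of Rcan1. The median 95% interval reached 3.85 to either side, and 0.959 for the 967 genes with a mean of 10 or more; in the test on shuffled values, 2.94% of the 2-fold changes at that mean were recovered.

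**Figure D4:**
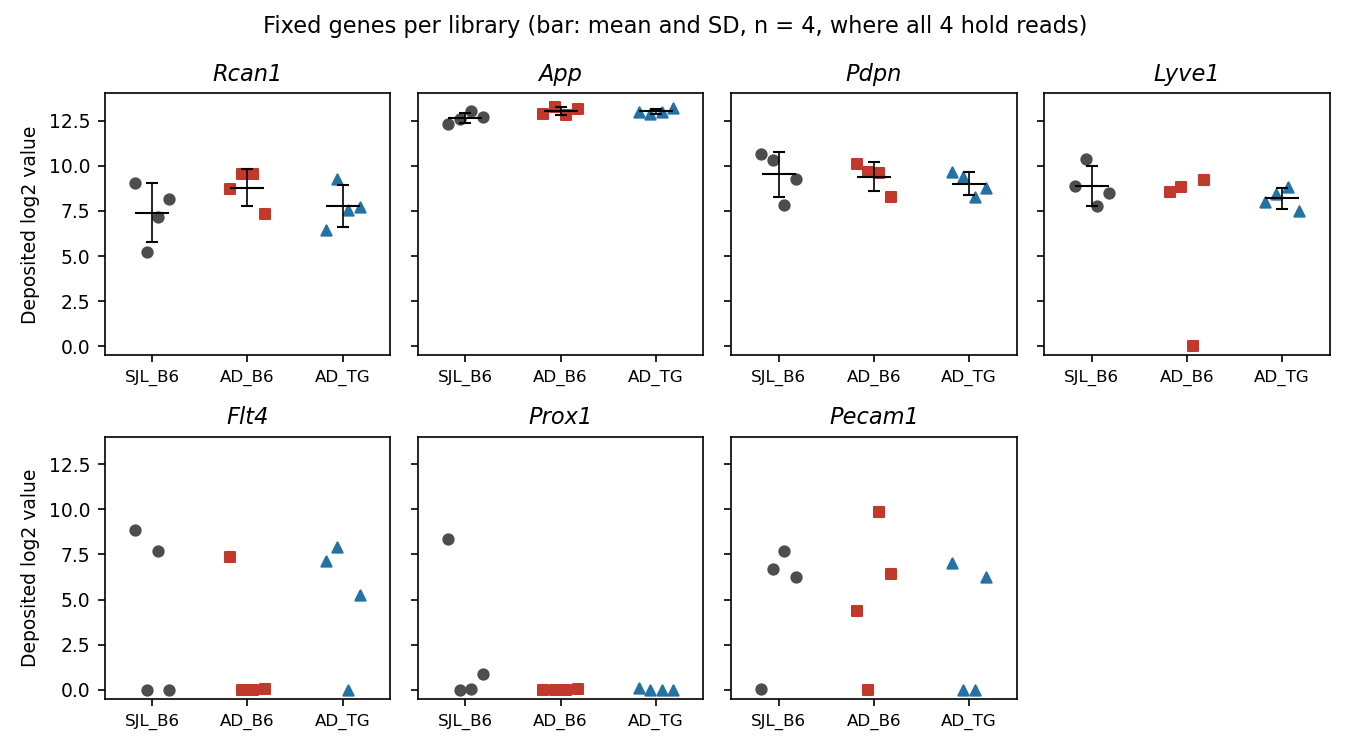
Deposited log2 value (vertical axis) of the 7 genes reported for every contrast, 1 point per library by group, with a bar for the mean and SD where all 4 libraries of a group hold reads. App lies between 12.33 and 13.27 in all 12 libraries, while Flt4, Prox1 and Pecam1 have libraries at 0 or below the value of 1 read in each group.

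The comparison of AD_TG with AD_B6 is the one the title is about, with and without the TG label. The titles differ in the B6 label as well, so a difference that goes with TG cannot be told apart from one that goes with B6. Genes of inflammation and interferon response were mostly higher in AD_TG: all 12 tested inflammatory cytokine genes and 11 of 13 interferon response genes, which averaged 7.30 ± 0.77 against 5.62 ± 0.95 (SD, n = 4). Rsad2, the antiviral gene viperin, ran from 7.33 to 9.22 in AD_TG, whereas AD_B6 held 6.25 and 7.54 and was listed at 0 or below 1 read in the other 2 libraries. Gbp2, a guanylate-binding protein, ran from 7.77 to 9.87 in AD_TG; in AD_B6 it was listed at 0 in 1 library and ran from 5.03 to 9.06 in the rest. Nfkbia, the inhibitor of NF-kappa B, stood at 11.82 ± 0.68 against 10.90 ± 0.33 and Il1b at 8.97 ± 0.83 against 8.67 ± 0.78. For the interferon response, camera gave an unadjusted p of 0.0825 (adjusted p = 0.941) and the exact permutation test of the list means 0.0571; for inflammatory cytokines, the exact test gave 0.143. The fewer genes with reads in AD_B6 apply to these lists too. After subtracting each library's mean over all genes tested, the interferon response differed by 1.04 and inflammatory cytokines by 0.96 (exact permutation p of 0.0571 and 0.257).

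Of the 14 calcineurin-NFAT components, 10 were lower in AD_TG, with a list mean of 7.76 ± 0.23 against 8.06 ± 0.48 (SD, n = 4; Rcan1 itself is 1 of the 14). Ppp3ca, the catalytic subunit of calcineurin, differed by -0.01 (SE 0.50), Ppp3r1, its regulatory subunit, by -0.08 (SE 0.44) and Akap5, which anchors it, by -0.44 (SE 0.37). In the other direction, the transcription factor gene Nfatc4 had reads in 3 AD_TG libraries, at 6.82, 7.73 and 7.90, and in 1 AD_B6 library, at 0.75. Camera gave an unadjusted p of 0.0587 (adjusted p = 0.941), and the exact permutation test of the list means gave 0.314. Of the 9 lymphatic endothelial genes, 6 were higher, with a list mean of 6.96 ± 0.86 against 5.59 ± 0.39 and an exact permutation p of 0.0857. After subtracting each library's mean over all genes tested, the list differed by 0.74 (exact permutation p of 0.171). Its median difference of 0.34 lay below the median of 0.41 over all genes tested. Itga9 ran from 5.64 to 8.48 in AD_TG, Nr2f2 differed by -0.01 (SE 0.51) and Foxc2, a factor of lymphatic valves, stood at 8.50 ± 0.67 against 8.36 ± 2.85. Of the 7 mural cell genes, 5 were higher (exact permutation p of 0.171 for the list means, and 0.457 after the same subtraction). Myh11, the smooth muscle myosin, ran from 5.60 to 9.43 in AD_TG and was at 0, 0, 1.25 and 2.92 in AD_B6; it passed adjusted over the list alone (adjusted p = 0.050 in limma) and had 0.871 over all genes. It no longer passed when SJL_B6 replicate 1, 3 or 4, AD_B6 replicate 1 or 2, or AD_TG replicate 1, 3 or 4 was left out, with values of 0.0579 to 0.171.

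Of the remaining cell type lists, the members higher in AD_TG were 15 of 16 for macrophage, 11 of 17 for pan-endothelial, 7 of 9 for astrocyte, 6 of 7 for choroid plexus, 5 of 6 for myelinating glia, 5 of 13 for meningeal fibroblast, 3 of 9 for neutrophil and granule, 3 of 8 for neuron, 2 of 5 for bone and cartilage, 1 of 7 for erythroid and 1 of 5 for pineal. Of the other lists, they were 16 of 17 for immediate early, 13 of 20 for amyloid processing and clearance, 9 of 10 for MHC class I, 6 of 7 for MHC class II, 8 of 11 for the NFAT and VEGF response, 8 of 14 for lymphangiogenic signalling, 8 of 12 for basement membrane, 7 of 12 for Notch and 7 of 13 for junctions. They were 8 of 14 for cholesterol synthesis, 6 of 10 for the unfolded protein response, 6 of 15 for glycolysis and hypoxia, 5 of 17 for nuclear oxidative phosphorylation and 3 of 8 for cell cycle. Of the neighbours of Rcan1, 13 of 14 were higher, among them the endocytic scaffold gene Itsn1 at 9.71 ± 0.72 against 6.90 ± 2.82 (SD, n = 4), with an exact permutation p of 0.114 for the list means. After subtracting each library's mean over all genes tested, the neighbours differed by 0.49 (exact permutation p of 0.457). None of the 31 lists passed camera, and the lowest adjusted p was 0.941. The median or mean differed in sign from camera in 9 lists, namely meningeal fibroblast, neuron, bone and cartilage, lymphangiogenic signalling, junctions, basement membrane, glycolysis and hypoxia, unfolded protein response and cholesterol synthesis, beside a median difference of 0.41 over all genes.

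App stood at 13.01 ± 0.15 in AD_TG and 13.02 ± 0.22 in AD_B6, and Pdpn at 9.01 ± 0.62 and 9.39 ± 0.79 (SD, n = 4). Lyve1 stood at 8.19 ± 0.59 in AD_TG, where AD_B6 replicate 3 was listed at 0. Flt4 had reads in 3 AD_TG libraries, at 5.27 to 7.91, and Pecam1 in 2, at 7.04 and 6.25. Prox1 had no AD_TG library at 1 read or more.

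The genes with the smallest unadjusted p included Hprt, the purine salvage enzyme, at 5.39 ± 1.15 in AD_TG and 8.83 ± 0.89 in AD_B6, and Pofut2, which adds fucose to secreted proteins, at 7.10 ± 1.57 and 10.20 ± 0.67 (SD, n = 4). Atl2, a membrane-shaping enzyme of the endoplasmic reticulum, stood at 6.66 ± 0.91 and 9.22 ± 0.62, and Jarid2, a partner of the Polycomb complex, at 7.18 ± 2.39 and 9.86 ± 0.51. Rgs9bp, an anchor of a photoreceptor signalling protein, ran from 7.18 to 9.70 in AD_B6 and had 2 AD_TG libraries with reads, at 8.85 and 1.02. C5ar1, the receptor of complement C5a, ran from 9.16 to 10.54 in AD_TG and stood at 9.09 and 1.25 in AD_B6 replicates 1 and 3, listed at 0 or below 1 read in the others. Dpysl2, which acts on microtubules, ran from 8.23 to 9.83 in AD_TG and was at 4.08, 3.22, 0 and 1.22 in AD_B6. Arid5b, a transcriptional co-regulator, stood at 7.50 ± 0.79 and R3hcc1l at 7.44 ± 0.67 in AD_TG, both listed at 0 or below 1 read in all 4 AD_B6 libraries. Gm21992 stood at 8.50 ± 1.49 in AD_TG.

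Limma called 0 of 11955 genes, with a lowest adjusted p of 0.871, and no other tool was run. There were 639 genes at an unadjusted p under 0.05, 519 higher and 120 lower in AD_TG, beside 597.75 expected by chance. Among the 4950 genes with reads in all 12 libraries, 130 were higher and 74 lower. The size of the imbalance moved with single libraries. Without AD_B6 replicates 1 to 4 there were 717, 618, 503 and 674 higher and 90, 99, 168 and 145 lower. Without AD_TG replicates 1 to 4 there were 347, 409, 404 and 365 higher and 145, 137, 137 and 140 lower. Without AD_B6 replicate 1 the lowest adjusted p was 0.0596, and over all alternatives it lay between 0.0596 and 0.966.

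AD_TG was set against SJL_B6 to see how far the libraries with the AD and TG labels stood from those with neither. These titles share no label, so a difference cannot be assigned to any of them. All 7 choroid plexus genes were higher in AD_TG (exact permutation p of 0.457 for the list means), which goes with SJL_B6 replicate 2, where Ttr stood at 13.38, beside 18.13 to 18.51 in the other SJL_B6 libraries and 18.15 ± 1.04 in AD_TG. All 7 MHC class II genes were lower (exact permutation p of 0.200), with Cd74 at 12.83 ± 0.16 against 13.26 ± 0.78 (SD, n = 4). Of the 13 interferon response genes, 9 were higher (unadjusted camera p of 0.0689, exact permutation p of 0.0857), among them Ifit2, an interferon-induced inhibitor of translation, at 6.98 to 8.45 in AD_TG and with 1 SJL_B6 library with reads, at 3.51. Of the 11 genes of the NFAT and VEGF response, 9 were higher (unadjusted camera p of 0.0952, exact permutation p of 0.114), with the phosphatase gene Dusp1 at 10.55 ± 0.75 against 8.89 ± 1.47. Of the 9 lymphatic endothelial genes, 6 were lower (exact permutation p of 0.371), and of the 14 neighbours of Rcan1, 11 were higher (0.229).

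Rcan1 differed by 0.35 (SE 1.04), App by 0.35 (SE 0.24), Pdpn by -0.51 (SE 0.69) and Lyve1 by -0.70 (SE 1.45). Flt4 had reads in 3 AD_TG libraries, at 5.27 to 7.91, and in 2 SJL_B6 libraries, at 8.82 and 7.69. Pecam1 had reads in 2 AD_TG libraries, at 7.04 and 6.25, and in 3 SJL_B6 libraries, at 6.24 to 7.67. Prox1 had no AD_TG library at 1 read or more and 2 SJL_B6 libraries with reads, at 8.38 and 0.88. Pofut2 stood at 7.10 ± 1.57 in AD_TG and 9.86 ± 0.16 in SJL_B6, and Hprt at 5.39 ± 1.15 and 9.03 ± 0.51 (SD, n = 4). Lrch4 stood at 4.99 ± 2.94 and 8.84 ± 1.17, Mthfd1, of folate metabolism, at 8.98 ± 0.30 and 4.88 ± 3.00, and Utp11l, of ribosome assembly, at 8.51 ± 0.56 and 1.81 ± 0.53. Cap2, an actin regulator, stood at 7.70 ± 0.61 in SJL_B6 and had no AD_TG library at 1 read or more. Mdp1, a phosphatase, ran from 7.68 to 8.30 in SJL_B6, and in AD_TG it was below 1 read in 1 library and at 0.82, 1.02 and 6.70 in the others. Scn8a, a sodium channel, ran from 8.22 to 9.45 in AD_TG and had 2 SJL_B6 libraries with reads, at 3.55 and 4.83. Gulp1 ran from 6.10 to 8.27 and Fam219b from 7.20 to 9.44 in AD_TG.

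Limma called 0 of 11955 genes (lowest adjusted p of 0.999, no other tool run), with 357 genes at an unadjusted p under 0.05, 220 higher and 137 lower in AD_TG, fewer than the 597.75 expected by chance. The balance depended on single AD_TG libraries, with 157 higher and 174 lower without replicate 1, 164 and 138 without replicate 2, 173 and 157 without replicate 3, and 154 and 136 without replicate 4. Without SJL_B6 replicates 1 to 4 there were 224, 223, 265 and 225 higher and 101, 128, 107 and 129 lower. The lowest adjusted p of camera over the 31 lists was 0.970. The median or mean differed in sign from camera in 7 lists, namely macrophage, mural cell, myelinating glia, Notch, amyloid processing and clearance, nuclear oxidative phosphorylation and unfolded protein response, beside a median difference of 0.08 over all genes.

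The last comparison asks whether genes that differ in AD_B6 return in AD_TG. No gene passed limma in both contrasts. At an unadjusted p under 0.05 in both, 201 genes were lower in AD_B6 than in SJL_B6 and higher in AD_TG than in AD_B6, 12 had the reverse pattern, and 0 had the same sign. R3hcc1l and Arid5b, with reads in all SJL_B6 and AD_TG libraries and in no AD_B6 library, were of the kind lower in AD_B6, as was Gm21992. Both contrasts share the AD_B6 libraries, and simulated unchanged groups gave 145 genes of opposite signs on average (120 to 173), against 213 observed. Independent lists would give 21.01 and 1.64 genes in these directions. Across genes, which are not independent replicates, the covariance of the differences was -2.03, beside -1.90 in the simulations (-1.999 to -1.83). With separate pairs of AD_B6 libraries for the contrasts, it lay between -0.0347 and 0.249 and the correlation between -0.0063 and 0.0431. With a library left out, the count ran from 145 (without AD_TG replicate 1) to 388 (without AD_B6 replicate 1). It was 304, 243 and 332 without AD_B6 replicates 2, 3 and 4, 164 to 186 without an SJL_B6 library, 167 to 169 without another AD_TG library, and 147 with a pseudocount of 50. Among the 4950 genes with reads in all 12 libraries it was 61.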

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

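The tests on Ttr, on transcript ends, on AD_B6 replicate 3 alone, on the groups behind the number of genes with reads, and the splits for counts of single genes were chosen after the result was seen, and the other tests before.

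Many genes had 100 or more reads in some libraries and were at 0 in others: of the 2826 genes whose median over the libraries with reads lay between 100 and 178 reads, 28.7% of entries were at 0, against 5.15e-44% from sampling of reads. The groups of the study are argued against, since pairs of libraries of 1 group shared the presence of reads no more than pairs of different groups (difference in mean correlation -0.0049, exact permutation p = 0.927 over 5775 ways of making the groups). Few RNA molecules sampled before amplification may contribute. Among 67 genes of complexes that every cell uses, at 100 or more reads, 19 of 804 entries (2.36%) were at 0, where sampling of reads gives 1.45e-28%. That share takes the level of a gene to be the same in all libraries, so any difference in level would raise it too. The labels state that 500 ng of total RNA entered each library and do not point to a shortage. The number of molecules was not measured. Libraries holding different kinds of cells may contribute as well, but the test of this cannot decide it. All 73 genes of complexes that every cell uses were at 0 in 3.31% of entries, below each of 10000 random sets matched on level (percentile 0, median 10.3%, range 5.25 to 17.1%). The level was the median over the libraries with reads, which leaves out the libraries at 0. Genes matched in this way can still differ in the number of RNA molecules, so the lower share does not need different cells. The libraries did differ in transcripts of other cell types, since the share of Ttr ran from 0.162 to 8.31% of a library. Ttr had reads in every library, so this does not show what put other genes at 0. For the entries at 0, both explanations stay open, and no value separates their shares.

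The 15 lymphatic endothelial genes were low beside genes of other cell types, in cells that magnetic sorting was meant to enrich. RNA from other cell types stays open and was not decided: Ttr alone exceeded the sum of the 15 genes in 12 of 12 libraries, by 2.12 to 192 times, which restates the pattern. Of the 7 choroid plexus genes, Clic6 is also on the list of neighbours of Rcan1, and Aqp1 and Otx2 are expressed elsewhere too; the levels of Ttr, Clic6 and Kl were 17.41 ± 1.90, 10.67 ± 1.85 and 10.04 ± 3.08 (SD, n = 12). Counting at transcript ends that misses lymphatic endothelial genes cannot be told apart from this, because 0 of the 15 genes were at 0 in every library, which leaves a partial loss of reads open. No biological explanation was tested, since the pattern is common to the 3 groups.

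AD_B6 had fewer genes with reads and more lower than higher genes. Lower sequencing depth of AD_B6 is argued against: at an equal depth of 4013140 reads, AD_B6 still had -1084 genes relative to SJL_B6 (-1142 as deposited) and AD_TG had 1291 more than AD_B6. AD_B6 replicate 3 alone is argued against for the lower genes, since without it 492 of 684 genes at an unadjusted p under 0.05 (71.9%) were lower in AD_B6. For the number of genes with reads it stays open: without it, AD_B6 had -628 genes relative to SJL_B6 (exact permutation p of 0.200) and AD_TG had 734 more than AD_B6 (0.143). The groups of the study stay open and cannot be told apart from differences between single libraries, with an exact permutation p of 0.0571 for AD_TG against AD_B6 and 0.0857 for AD_B6 against SJL_B6 in 4 against 4 libraries (0.321 adjusted).

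The 35 splits of the 8 libraries of a contrast into equal groups include the real one. For AD_B6 against SJL_B6, AD_TG against AD_B6 and AD_TG against SJL_B6, the real numbers of genes and of lists past the threshold were 0, so that all 35 splits reach them whatever the data, which says nothing about chance (limma, highest other 1, 4 and 1 genes, and 0 lists). For genes at an unadjusted p under 0.05, 24, 12 and 22 splits gave as many as the real 647, 639 and 357 (highest other 963, 820 and 540). Genes with reads in all 4 libraries of 1 group and in none of the other numbered 14, 22 and 9, as many in 13, 5 and 28 splits (highest other 19, 29 and 25). Chance is not excluded for the counts at an unadjusted p or for these genes. For the 213 genes of opposite signs at an unadjusted p under 0.05, 3 of 100 groupings of the 12 libraries gave as many. Of these groupings, 1 was the real one and the others were drawn at random (highest other 252). The share is under 0.05, but random groupings also reached the count. It rests on 100 groupings and was not adjusted for the other splits, so chance is not firmly excluded. The count does not show a reversal, since the contrasts share the AD_B6 libraries and it was not repeated with separate AD_B6 pairs. With such pairs, the correlation over all genes tested lay between -0.0063 and 0.0431. That shows no reversal across the genes as a whole and cannot decide it for a small part of them.

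A single library lay apart from the other 3 of its group, by a gap of most of the group's range, in 17 of 201 groups of values tested, where chance gives about 1 in 20. These were 13 of 93 for the named genes, many of which were named for a small p and have libraries at 0, 3 of 93 for the lists and 1 of 15 for the library measures; values below that of 1 read were taken as 0. In SJL_B6, this was Prox1 in replicate 1 (8.38, others 0 to 0.88), Fam219b in replicate 1 (9.41, others 0), Lrch4 in replicate 3 (7.09, others 9.32 to 9.57), the choroid plexus list in replicate 2 (6.36, others 11.71 to 12.04) and the tested members of the Notch list in replicate 3 (6.81, others 5.74 to 5.92). Over all members of that list, the replicate did not lie apart by this measure (5.84, others 5.13 to 5.46). In AD_B6 replicate 1, it was Flt4 (7.33, others 0), Pygl (10.03, others 8.95 to 9.02) and C5ar1 (9.09, others 0 to 1.25). In AD_B6 replicate 3, Lyve1 was at 0 (others 8.53 to 9.24), Jarid2 at 9.10 (others 10.10 to 10.17) and the tested members of the unfolded protein response list at 8.85 (others 7.90 to 8.04), which was also lost over all members (7.37, others 6.59 to 7.16). Cap2 was at 0 in AD_B6 replicate 2 (others 7.54 to 8.59) and Utp11l at 0 in AD_B6 replicate 4 (others 8.57 to 8.92). In AD_TG, it was Dpysl2 in replicate 3 (9.83, others 8.23 to 8.43), Rgs9bp in replicate 2 (8.85, others 0 to 1.02), Mdp1 in replicate 4 (6.70, others 0 to 1.02) and the share of Ttr in replicate 3 (1.53%, others 5.57 to 6.23%).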

How the results depend on the processing

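Array quality weights, the pseudocount of 50, the genes with reads in all 12 libraries, the removal of Rn45s, Rn4.5s and Ttr, the weights without AD_B6 replicate 3, the lists with a library left out and the exact tests of list means were chosen after the data were seen. The 87 recomputed counts of genes in limma were 0, with unadjusted counts of 245 to 883 for AD_B6 against SJL_B6, 204 to 819 for AD_TG against AD_B6 and 151 to 578 for AD_TG against SJL_B6; the smallest come from the 4950 genes with reads in all 12 libraries. The lowest adjusted p lay between 0.272 and 0.995, 0.0596 and 0.966, and 0.747 and 1. No list passed in camera with a preset correlation (10 unadjusted p under 0.05, lowest adjusted p 0.106), with another scaling or with a library left out. None passed in the exact permutation tests either (lowest adjusted p 0.531). Their smallest p is 0.0286, with which a single list cannot pass after adjustment over 31 lists, so they do not check the calls. Without a library, the camera p of the lymphatic endothelial list in AD_B6 against SJL_B6 ran from 0.0395 to 0.1503. Of 979 recomputed values of named genes, 955 kept their sign, and 0 passed. The DESeq2 Wald test and limma voom with quality weights were not run, because they need counts.

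The replicate numbers did not pair the libraries: the correlation of deviations was -0.0153 to 0.067 for 12 pairs of the same number and -0.0703 to 0.0621 for 36 others, and the best match was the own number in 6 of 24 cases. With the replicate block, limma called 0 genes in each contrast (unadjusted 685, 685 and 376) and camera 0 lists, so it changed no call.

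The differences that changed sign, none of which passed before or after, were as follows, and the cause was not tested. In AD_B6 against SJL_B6, Pdpn became 0.0833 with array weights and 0.0907 with weights and without AD_B6 replicate 3, and ran from -0.68 to 0.2555 with a library left out. Pecam1 became -0.0076 with upper-quartile scaling, -0.0455 with the pseudocount of 0.1, and -1.03 and -1.9985 with the weights, with and without AD_B6 replicate 3, and ran from -1.71 to 1.7263 with a library left out. In AD_TG against AD_B6, App became 0.0113 with upper-quartile scaling and ran from -0.0867 to 0.0697 with a library left out. The weights without AD_B6 replicate 3 gave -0.68 for Lyve1 and 0.54 for Pecam1. With a library left out, Lyve1 ran from -0.67 to 2.4123, and the negative value came without AD_B6 replicate 3. In AD_TG against SJL_B6, Flt4 became -0.10 with the pseudocount of 50 and ran from -0.42 to 2.6497 with a library left out, and Rcan1 from -0.38 to 0.8974. Rcan1 in AD_TG against AD_B6 stayed negative, at -1.55 to -0.61 with a library left out.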

Other observations

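The tests on App and on the sex-linked genes were chosen after the result was seen, and the genes of the next paragraph were named after their values were seen.

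Transcripts of further cell types were abundant in all 12 libraries. Hba-a1, a haemoglobin chain of red blood cells, stood at 12.98 ± 1.04 (SD, n = 12). Tph1, the first enzyme of serotonin synthesis and abundant in the pineal gland, stood at 12.43 ± 1.06, and Rom1 and Sag, of photoreceptors and the pineal gland, at 11.17 ± 0.86 and 10.21 ± 1.14, whereas Aanat and Asmt, which make melatonin, had reads in 1 and 2 of the 12 libraries. Ttr was lowest in SJL_B6 replicate 2 at 13.38 and AD_B6 replicate 1 at 13.92, and ran from 16.59 to 19.18 in the others. Immediate early genes stood highest in the replicate 2 libraries of AD_B6 and AD_TG, with Egr1 at 12.84 and 13.82 and Nr4a1 at 12.05 and 11.89.

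Among sex-linked genes, Ddx3y, of the Y chromosome, had reads in all 12 libraries (9.55 ± 0.81, SD, n = 12), and Xist, the RNA of the inactive X chromosome, in 7, at up to 8.10. Xist had reads in 4 SJL_B6, 1 AD_B6 and 2 AD_TG libraries, and Eif2s3y, of the Y chromosome, in 4, 2 and 4. The mean of the 4 Y-linked genes was 5.33 ± 0.80 in SJL_B6, 5.62 ± 2.10 in AD_B6 and 7.37 ± 1.12 in AD_TG (SD, n = 4), with exact permutation p-values of 0.0571 for AD_TG against SJL_B6, 0.257 for AD_TG against AD_B6 and 0.771 for AD_B6 against SJL_B6. For Xist they were 0.600, 0.343 and 0.0571. All 4 SJL_B6 libraries thus had reads of both Xist and Ddx3y. The labels give no sex of the animals, so a difference in sex between the groups cannot be told apart from one that goes with their titles.

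As a hypothesis, App may be higher with the AD label, through a difference that goes with it. The 8 libraries with that label had 13.01 ± 0.17 (SD, n = 8) and SJL_B6 12.66 ± 0.29 (SD, n = 4), a difference of 0.36, with an exact two-sided permutation p of 0.0222 over 495 splits. Limma tested AD_B6 and AD_TG against SJL_B6 apart, and App passed in neither, with adjusted p-values of 0.872 and 0.999 over all genes. The difference of the 8 pooled libraries was not tested in limma, and its exact p was not adjusted over genes. A test chosen after the values were seen is no independent evidence. Only SJL_B6 carries the SJL label, so the difference cannot be told apart from one that goes with that label.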
